A study of Xenopus laevis with 42 samples.

How the data were processed

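Messenger RNA from embryos of the frog Xenopus laevis was sequenced on an Illumina NextSeq, per the labels. One blastomere of the 8-cell embryo, D1, the dorsal-animal cell whose descendants contribute to the neural plate, was followed in 2 ways. It was either filled with a fluorescent dye and its descendants were dissected from the growing embryo (called progeny here), or it was removed and kept apart from the embryo (called explant here). Each tissue was sampled at 7 stages, which the labels give as 8-cell, 16-cell, 32-cell, blastula, gastrula, early neurula and mid neurula. The sample descriptions abbreviate the last stage in a way that does not match the title, and the title was followed. The labels list 42 samples in 14 groups of 3, numbered by frog. They do not say whether equal numbers in both tissues mean the same animal.

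The authors deposited 2 tables, 1 per tissue, with 44962 rows each in the same order. Per the file headers the values are TPM (a transcript abundance scaled to a fixed total), which the authors made before deposit. Each table holds 7 columns, 1 per stage, so the 3 samples of a group had already been combined into 1 pooled value. How they were combined is not given in the sources used here. The submitters' processing notes name TopHat, Bowtie2, Cufflinks and Cuffdiff without versions, and the genome build and annotation are not given in the sources used here. The columns sum to between 995987 and 999092, so each was scaled to nearly the same total within itself. The 2 tables carry no scaling across tissues beyond this, and every comparison of explant with progeny sets levels from separate tables side by side. TPM keeps no trace of the number of reads, so the depth is unknown and no interval for counting error can be given. Between 28521 and 36651 rows per column were above 0.

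The unit of analysis differed from what the design had assumed. The design, written before the data were examined, planned limma on log2(TPM + 1) over 42 libraries with an adjusted p for each gene. With 1 pooled column per group there is no replicate spread, so no test, p-value or standard deviation across samples was computed, and no difference reported here has a replicate check. A rule of size took the place of the test. A row counts as higher or lower, or as having risen or fallen, when log2(TPM + 1) differed by at least 1, which is 2-fold on that scale. The pseudocount of 1 understates the change of rows with low values. Rows were kept when at least 1 of the columns fitted reached 1 TPM, which left 25062 rows for progeny, 24374 for explant and 26351 for comparisons of both tissues. The 19 comparisons are 5 stage intervals within each tissue, explant against progeny at 7 stages, the mean of that difference over gastrula and both neurula stages, and the difference between the tissues in their change from gastrula to mid neurula.

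Gene symbols are those of the row names, in which a final L or S marks the homeolog of the long or the short subgenome of this allotetraploid species. Homeologs have similar sequences and how reads were divided between them is not given in the sources used here, so a value of 1 copy can hold reads of the other. Of the rows, 24567 carry a symbol. There are no coordinates in the tables, and none are printed. Of 36 anchor symbols 4 had no row, krt12.4, sox17b, tbxt and ventx2.1. Synonyms in the RefSeq table of assembly Xenopus_laevis_v10.1 pair tbxt with the rows t.L and t.S, which were chosen after their values were seen.

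There were 29 gene lists fixed before the data were examined. They cover maternal oocyte factors, germ plasm, first zygotic genes, pan-neural plate, anterior neural plate and eye field, posterior neural genes, neuronal differentiation, neural crest, placode, epidermis, ciliated cells, cement gland, ionocytes, organizer and notochord, somite and muscle, ventral and lateral mesoderm and blood, endoderm, targets of BMP, FGF, Wnt and Notch signalling, cell cycle, ribosomal proteins, oxidative phosphorylation, glycolysis, stress and immediate early response, p53 and apoptosis, histone genes and the mitochondrial genome. The list of the mitochondrial genome matched 0 rows, which left 28. Some genes are on more than 1 list, such as cer1 on the endoderm and the organizer lists. For each list the number of members higher, lower and under 2-fold is given with the median log2 difference. The median was also placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside percentiles 2.5 to 97.5 is said to stand apart, as a description of these columns and not as a test.

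Genes were named by a rule written before the data were examined. It takes the anchor genes, the 8 rows with the highest and the 8 with the lowest difference for explant against progeny at gastrula, at each neurula stage and on average, 4 and 4 in other comparisons, and up to 3 per list. The row must have a symbol and at least 5 TPM in its higher column, and as added here, rows at exactly 0 in a compared column are not ranked. The parts of the rule that needed replicates fell away. The row sox17a.L, the rows with suspect zeros and the pair cdh1 are outside this rule and were chosen after their values were seen.

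The scripts used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. The rule of size was tested on simulated data, made from the progeny early neurula column and the spread seen between the tissues at 16-cell, over 20495 rows. It recovered 42% of 50 rows changed 2-fold and 100% of 50 rows each changed 4-fold, 8-fold and 16-fold, and called 0.069% of 20295 unchanged rows. The changed rows were at 10 TPM or more, and the noise was normal with the spread of rows averaging above 10 TPM. The real 16-cell comparison passed the rule in 674 of 26351 rows, so the simulated share of false calls does not carry over to these data. Of 200 unchanged lists 5.5% fell outside the percentile limits. These lists were random draws with independent noise per row, so a share near that of the limits was built in. The real lists hold homeolog pairs and related genes, so this share does not carry over to them. Other settings fixed beforehand that could be run were a pseudocount of 0.1, no filter on low values, scaling of all 14 columns by the median of ratios and, for the lists, summing of homeologs.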

Results

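The data are 14 pooled transcript profiles of the D1 lineage of Xenopus laevis, 7 of progeny dissected from the embryo and 7 of explants kept apart from it, each made from 3 samples. Ages run from 2 hours 15 minutes at 8-cell (Nieuwkoop-Faber stage 4) to 18 hours at mid neurula (stage 17). Depth is unknown for every profile. There is 1 value per gene, tissue and stage, without replicates, so no difference could be set against the spread between frogs. Levels of explants and progeny are set across 2 separately scaled tables. As a yardstick within the data, log2 differences between the tissues had a standard deviation across rows of 0.48 at 8-cell, 0.31 at 16-cell, 0.32 at 32-cell and 0.32 at blastula among rows averaging at least 10 TPM. It was 0.56 at gastrula, 1.197 at early neurula and 1.17 at mid neurula.

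The first question is how the transcriptome of the D1 lineage changed inside the embryo. During cleavage few rows moved. From 8-cell to 32-cell 258 rows rose and 149 fell, and from 32-cell to blastula 559 rose and 118 fell. Maternal oocyte factors were mostly under 2-fold, in 30 and 28 of 31 rows, with medians of -0.16 and -0.17. The row ccna1.L, a cyclin of early cleavage cycles, was at 3422 TPM at 8-cell and 2477 at blastula, and ccnb5.L, another maternal cyclin, was at 2208 and 1685. The rows named by rank included pex14.S, which went from 11.2 to 49.97 TPM between 8-cell and 32-cell, and dsg4.L, which went from 8.70 to 0.0093. From 32-cell to blastula pbk.L, a mitotic kinase, fell from 67.4 to 17.4 TPM and mad2l1.L, a spindle checkpoint protein, from 90.2 to 27.96. With median-of-ratios scaling the split of these counts turned, to 111 higher and 242 lower for the first interval and 151 higher and 212 lower for the second, so the balance of rises and falls in cleavage depends on the scaling.

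Between blastula and gastrula, across the onset of zygotic transcription, 4232 rows rose and 7779 fell in progeny. Of 31 maternal oocyte factors 23 fell and 6 rose, with a median log2 change of -3.30. The cyclins ccnb5.L and ccna1.L fell to 24.9 and 42.6 TPM, and cpeb1.S, which controls translation of stored messages, fell from 425 to 6.04. Of 27 first zygotic genes 26 rose, with a median of 4.96, and gs17.L went from 0.27 to 1052 TPM. Organizer and notochord genes rose in 28 of 33 rows and endoderm genes in 25 of 26. Pan-neural plate genes rose in 22 of 34 rows, with sox2.S at 174.5 TPM and sox3.S at 459.5 at gastrula. Ribosomal protein genes rose in 105 of 119 rows, with a median of 1.81. The hyaluronan synthase has1.S had the highest rank, from 1.65 to 3206 TPM. Median-of-ratios scaling gave 5683 rises and 5226 falls.

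From gastrula to early neurula 4653 rows rose and 4131 fell in progeny. Somite and muscle genes rose in 28 of 34 rows, with a median of 2.63: actc1.L, a muscle actin, went from 0.56 to 1241 TPM, and atp2a1.L, the calcium pump of muscle, from 0.16 to 337. Anterior neural plate and eye field genes rose in 29 of 43 rows, with the retinal regulator rax.L going from 0.86 to 129.0 TPM and six3.L from 1.31 to 85.7. Posterior neural genes rose in 29 of 40 rows, neural crest genes in 20 of 25 and cement gland genes in 7 of 8, with a median of 4.95 and agr2.L at 922 TPM. First zygotic genes fell in 22 of 27 rows and endoderm genes in 15 of 26. The pluripotency factor pou5f3.2.L fell from 1316 to 19.6 TPM, and cer1.S, a secreted antagonist from anterior endoderm, from 467 to 13.2.

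From early to mid neurula 2048 rows rose and 390 fell in progeny. Neuronal differentiation genes rose in 19 of 36 rows, with none lower, and tubb3.L, a neuronal tubulin, went from 0.67 to 25.7 TPM. Among those with the highest rank were syt13.S, a synaptotagmin, from 0.0401 to 16.9 TPM, and slc1a3.L, a glutamate transporter, from 3.1 to 58.8. Somite and muscle genes rose in 14 of 34 rows and ionocyte genes in 7 of 17. Organizer and notochord genes fell in 14 of 33 rows and endoderm genes in 10 of 26, and pou5f3.1.L fell from 210.1 to 36.0 TPM. Median-of-ratios scaling gave 1520 rises and 688 falls.

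The same intervals were read in explants. From 8-cell to 32-cell 2083 rows rose and 159 fell, and from 32-cell to blastula 1398 rose and 216 fell. The 8-cell explant column stood apart: against the 16-cell column in its place, 54 rows rose and 22 fell by 32-cell. The rows with the highest rank were low at 8-cell and not in the other cleavage columns, such as foxh1.S, a nodal signal transducer stored in the egg, at 0.26 TPM at 8-cell, 46.0 at 16-cell and 52.7 at 32-cell, and ephx4.S at 0.13, 59.9 and 57.7. Median-of-ratios scaling gave 621 rises and 838 falls for the first interval and 368 and 475 for the second.

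From blastula to gastrula the explants lost maternal messages and gained first zygotic transcripts, as 3874 rows rose and 7342 fell (5173 and 4826 with median-of-ratios scaling). Maternal oocyte factors fell in 21 of 30 rows, with a median of -2.92, and all 27 first zygotic genes rose, with a median of 4.23. Pan-neural plate genes rose in 21 of 33 rows and epidermal genes in 22 of 32, with a median of 3.86. Somite and muscle genes rose in 3 of 31 rows. The BMP target id3.S went from 0.18 to 1094 TPM.

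From gastrula to early neurula 4251 rows rose and 5398 fell in explants, or 5452 and 4209 with median-of-ratios scaling. Pan-neural plate genes fell in 20 of 33 rows and rose in 2, with a median of -1.64. The other neural lists are not reported here for this interval in explants. The neural plate factor zic1.L went from 58.7 to 2.2 TPM and sox3.S from 378 to 66.1. Ciliated cell genes rose in 24 of 31 rows, with a median of 2.23, epidermal genes in 19 of 32, ionocyte genes in 9 of 17 and BMP targets in 12 of 24. The epidermal lectin itln1.L went from 1.23 to 1606 TPM. Cement gland genes rose in all 8 rows, with agr2.S at 1578 TPM. Cell cycle genes fell in 29 of 53 rows, with ccnb1.S going from 120.7 to 1.64 TPM.

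From early to mid neurula 1973 rows rose and 327 fell in explants (1534 and 583 with median-of-ratios scaling). Somite and muscle genes rose in 17 of 31 rows, with a median of 1.21, and took the first ranks: actc1.L went from 1.39 to 61.2 TPM and mylpf.S, a fast muscle myosin light chain, from 0.33 to 22.9. Anterior neural plate and eye field genes rose in 12 of 34 rows and fell in 1, with rax.L going from 7.72 to 31.4 TPM and six3.L from 15.9 to 33.7. Pan-neural plate genes rose in 9 of 33 rows and organizer and notochord genes in 9 of 32, or in 5 and 6 with median-of-ratios scaling. The shear-responsive factor klf2.S had the lowest rank, from 39.1 to 4.37 TPM.

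The central question is whether D1 descendants express the same genes apart from the embryo as in it. Before zygotic transcription the profiles were close, though least so at 8-cell. There 1596 rows were 2-fold apart, against 1481 at gastrula, or 968 against 1020 among rows reaching 5 TPM. Counts of rows at least 2-fold higher and lower in explants were 501 and 1095 at 8-cell, 287 and 387 at 16-cell, 349 and 431 at 32-cell, and 377 and 386 at blastula, where a pseudocount of 0.1 gave 1118 and 1070. Median-of-ratios scaling changed the 8-cell split to 897 higher and 763 lower. Across rows, which are not independent replicates, Pearson's r of log2(TPM + 1) between the tissues was 0.978 at 8-cell, 0.988 at 16-cell, 0.987 at 32-cell and 0.987 at blastula. The value at gastrula was 0.973. A few rows differed widely at all 4 stages. The oxidase organizer noxo1.L was at 286 TPM in the 8-cell explant and 0.0193 in the 8-cell progeny, and at 65.2 against 0.044 at blastula. The muscle protein gene myot.L was at 57.6 against 0.11 TPM at 8-cell, and asf1a.L, a histone chaperone, at 28.9 against 0.42 at blastula. The glucuronosyltransferase ugt1a6.S was at 33.9 TPM in blastula progeny and 0.038 in explants, and spint1.S at 26.2 against 1.16. Ribosomal protein genes had medians of 0.71, 0.59, 0.58 and 0.33 at these stages, above 0 at each of them with either scaling, while 18, 4, 11 and 2 of 119 rows were 2-fold higher and 0 were lower. With median-of-ratios scaling the 8-cell count was 60.

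**Figure D1:**
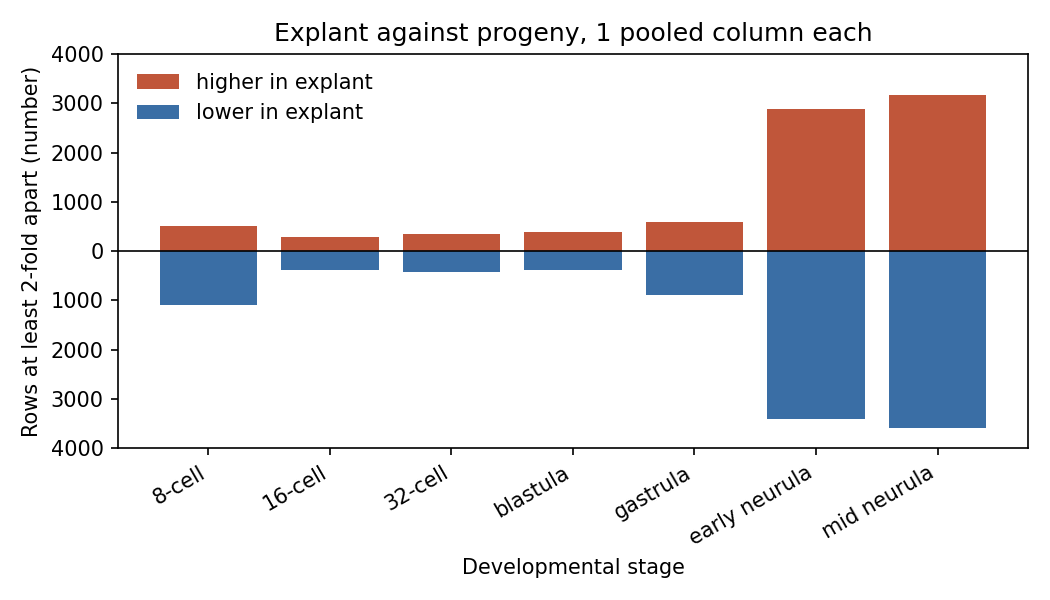
Number of rows at least 2-fold higher in explants (bars above 0) or lower in explants (bars below 0) than in progeny at each of the 7 stages, from 1 pooled column per tissue and stage. The bars hold 377 and 386 rows at blastula and 3158 and 3589 at mid neurula.

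At gastrula 581 rows were higher and 900 lower in explants. The lowest named rows, in order, were myf5.L, a muscle determination factor, at 63.1 TPM in progeny and 0.13 in explants, pnhd.S at 103.7 and 0.91, and hoxd1.S at 98.1 and 1.13. Next came myod1.S at 70.1 and 0.72 TPM, tbx6.L, a factor of the paraxial mesoderm, at 59.2 and 0.56, and myf5.S. Behind them were wnt8a.S at 41.3 and 0.17 TPM and msgn1.L at 36.8 and 0.080. Endoderm genes were lower in 23 of 26 rows, with a median of -1.98. Organizer and notochord genes were lower in 15 of 33 rows, with chrd.S, a BMP antagonist of the organizer, at 286.7 TPM in progeny and 102.3 in explants. The row t.L, brachyury, was at 270.4 and 16.0 TPM, and vegt.L at 423 and 72.8. FGF targets were lower in 9 of 18 rows and Wnt targets in 9 of 22, with sp5.L at 51.6 and 1.03 TPM.

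Among neural genes at gastrula, those of the pan-neural plate were lower in 6 of 34 rows, with a median of -0.47, and sox2.S was at 174.5 TPM in progeny and 137.1 in explants. Anterior neural plate and eye field genes were lower in 4 of 44 rows and higher in 1, and otx2.L was at 110.6 and 91.6 TPM. Posterior neural genes were lower in 15 of 40 rows, with a median of -0.44, and neural crest genes in 7 of 25, with a median of -0.63. Epidermal genes were higher in 14 of 33 rows and lower in 0, and BMP targets were higher in 9 and lower in 5 of 24. The highest named rows included szl.L, a BMP-induced secreted inhibitor, at 12.7 TPM in progeny and 131.4 in explants, foxi1.S, an ionocyte regulator, at 10.2 and 91.5, and foxi4.2.L at 58.2 and 416.

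At early neurula the counts were 2881 higher and 3410 lower, or 3364 and 3200 with median-of-ratios scaling, and r across rows fell to 0.880. Muscle was the most reduced list, lower in 33 of 34 rows with a median of -4.43. All 8 rows with the lowest rank encode muscle proteins, among them actc1.L at 1241 TPM in progeny and 1.39 in explants, myl1.S at 405 and 0.21, and atp2a1.L at 337 and 0.32. Pan-neural plate genes were lower in 32 of 34 rows, with a median of -2.34: sox2.S was at 327.6 and 74.7 TPM, sox3.S at 323 and 66.1, zic1.L at 38.8 and 2.2, and irx3.S at 55.9 and 0.36. Anterior neural plate and eye field genes were lower in 33 of 44 rows, with rax.L at 129.0 and 7.72 TPM, pax6.L at 66.9 and 5.94 and otx2.L at 147.1 and 59.7. Posterior neural genes were lower in 36 of 40 rows and neural crest genes in 21 of 25, with snai2.L at 91.3 and 4.83 TPM and pax3.L at 61.0 and 0.54. Organizer and notochord genes were lower in 31 of 33 rows, with chrd.S at 263 and 23.0 TPM and shh.L at 41.2 and 3.58.

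Epidermal lists went the other way at early neurula. Ciliated cell genes were higher in 25 of 31 rows, with a median of 2.44, and foxj1.S, the regulator of motile cilia, was at 15.3 TPM in progeny and 187.6 in explants. Epidermal genes were higher in 24 of 33 rows and lower in 3, of which krt5.7.L and krt5.7.S were listed at 0 in explants, with krt12.S at 731 and 5323 TPM, dlx3.S at 44.9 and 337.0 and tp63.S at 15.7 and 75.9. Ionocyte genes were higher in 12 of 17 rows, with ca12.L at 4.78 and 148.9 TPM. BMP targets were higher in 18 of 24 rows, with szl.L at 32.4 and 1136 TPM and bambi.L at 62.3 and 530.4. Other rows of the highest rank were tnfsf10l.L at 3.69 and 216.4 TPM, slc6a3.S at 4.62 and 166.3, and klf2.L at 0.77 and 42.4. Notch targets were lower in 9 of 15 rows, FGF targets in 15 of 18 and cell cycle genes in 14 of 53.

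At mid neurula 3158 rows were higher and 3589 lower, and r was 0.874. The split turned to 3553 and 3109 with median-of-ratios scaling and to 2620 and 2567 among rows reaching 5 TPM. Between the neurula stages 2387 of the higher rows and 2371 of the lower rows were shared, where independent lists would share 345.3 and 464.4. These stages lie close together, with r across rows of 0.964 in progeny and 0.968 in explants. Sharing above independence is therefore no replicate check. Somite and muscle genes were lower in all 34 rows, with a median of -3.74. Neuronal differentiation genes were lower in 29 of 36 rows, with tubb3.L at 25.7 TPM in progeny and 0.34 in explants. Neural crest genes were lower in 21 of 25 rows, with a median of -2.95 and sox10.L at 43.2 and 0.0150 TPM. Pan-neural plate genes were lower in 30 of 34 rows, with a median of -1.58, and sox2.S was at 209.6 and 100.2 TPM. Anterior neural plate and eye field genes were lower in 28 of 44 rows, yet six3.L, at 41.7 and 33.7 TPM, and otx2.L, at 111.3 and 85.5, were less than 2-fold apart.

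Ciliated cell genes were higher in 26 of 31 rows at mid neurula, ionocyte genes in 13 of 17, epidermal genes in 25 of 33 and BMP targets in 15 of 24. The row krt12.S reached 6538 TPM in explants against 1282 in progeny, and ccno.L, needed for multiciliated cells, 182.4 against 6.72. Cement gland genes were under 2-fold in all 8 rows, with agr2.S at 1516 TPM in progeny and 2108 in explants. Endoderm genes were lower in 6 of 26 rows, and organizer and notochord genes in 13 of 33. Among glycolysis genes 10 of 27 were lower and 5 higher: eno1.L was at 548.4 and 26.4 TPM, gapdh.S at 675 and 75.8, and hk2.S at 17.5 and 140.6.

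**Figure D2:**
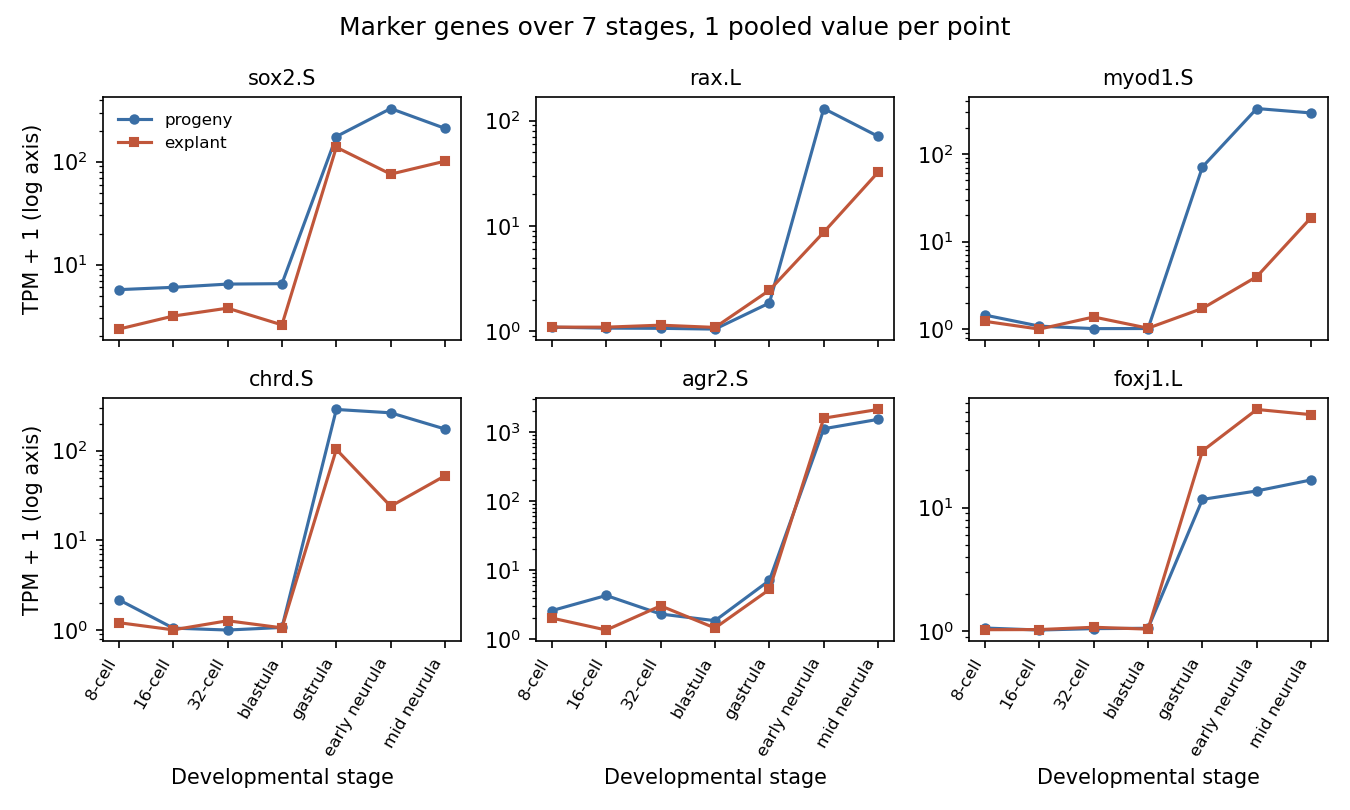
TPM plus a pseudocount of 1 on a log axis (vertical) against developmental stage (horizontal) for 6 genes, with circles for progeny and squares for explants, 1 pooled value per point and no error bars. At mid neurula sox2.S was at 209.6 TPM in progeny and 100.2 in explants, myod1.S at 293.1 and 17.8, and agr2.S at 1516 and 2108.

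Averaged over gastrula and both neurula stages, 1958 rows were higher and 2098 lower in explants. The split turned to 2186 and 2020 with median-of-ratios scaling and to 1563 and 1488 with homeologs summed. The highest named rows were szl.L, tnfsf10l.L, szl.S and foxi1.S, at mean log2 differences of 4.29, 4.03, 3.95 and 3.79, and the lowest were myod1.S, myl1.L and actc1.S at -5.24, -5.16 and -5.07. Of 28 lists 23 stood apart from matched random lists, 9 above and 14 below. Those above with members mostly past 2-fold were ciliated cells (25 of 31 rows higher, median 1.75), ionocytes (11 of 17, 1.53), epidermis (21 of 33, 1.46) and BMP targets (14 of 24, 1.23). The other 5 above had medians of 0.05 to 0.29 and few members past 2-fold: oxidative phosphorylation (0 of 119), histone genes (0 of 24), p53 and apoptosis (2 of 24 higher), stress and immediate early response (9 of 48 higher and 4 lower) and maternal oocyte factors (4 of 31 higher and 4 lower).

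The lists below were somite and muscle (34 of 34 rows lower, median -3.39), neural crest (19 of 25, -1.80), posterior neural (34 of 40, -1.52), pan-neural plate (28 of 34, -1.42), organizer and notochord (27 of 33, -1.40), endoderm (15 of 26, -1.31), FGF targets (12 of 18, -1.19), Wnt targets (11 of 22, -1.15), anterior neural plate and eye field (24 of 44, -1.03), neuronal differentiation (15 of 36, -0.94), Notch targets (6 of 15, -0.85), placode (10 of 22, -0.63), cell cycle (1 of 53, -0.34) and ribosomal proteins (0 of 119, -0.24). Within the placode list 6 rows were higher, among them sox7.L, which is also an endothelial gene, and foxi4.2.L. The 5 lists inside the limits were first zygotic genes, germ plasm, cement gland, glycolysis, and ventral and lateral mesoderm and blood, with medians of -0.17, -0.11, -0.49, 0.05 and -0.16.

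**Figure D3:**
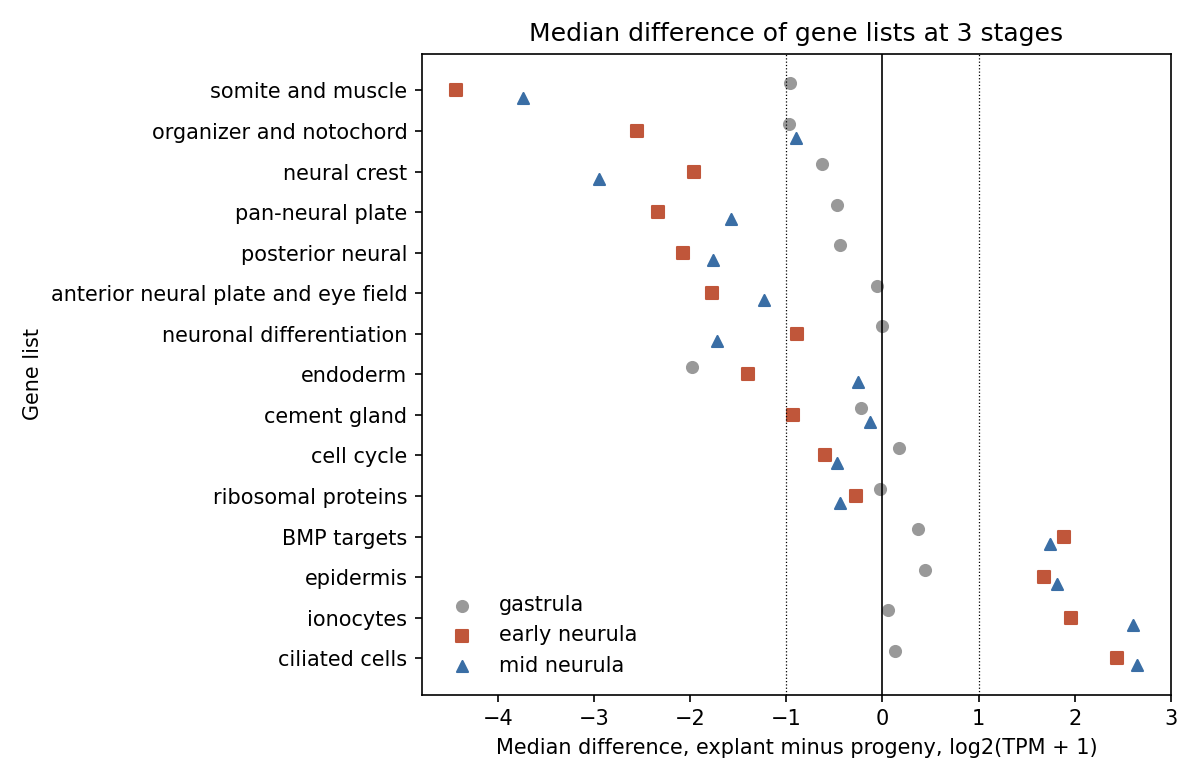
Median difference in log2(TPM + 1), explant minus progeny (horizontal), of 15 gene lists (vertical) at gastrula (circles), early neurula (squares) and mid neurula (triangles), with dotted lines at 2-fold. The somite and muscle list lies at -4.43 at early neurula and the ciliated cell list at 2.44.

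The change from gastrula to mid neurula was then set side by side in the tissues. It differed by at least 2-fold in 7344 rows, with the signed change more positive in explants in 3264 and in progeny in 4080 (3943 and 3158 with median-of-ratios scaling). It was more positive in explants for 22 of 31 ciliated cell rows and 12 of 17 ionocyte rows. The same sign in 21 of 26 endoderm rows included genes that fell less in explants, from a lower gastrula level: sox17a.L went from 72.4 to 12.3 TPM in progeny and from 16.1 to 7.68 in explants. It was more positive in progeny for 26 of 36 neuronal differentiation rows, 24 of 44 anterior neural rows and 23 of 34 somite and muscle rows. The rows of the highest and lowest rank were val.L, which went from 0.60 to 507 TPM in explants and from 10.3 to 16.1 in progeny, and act3.S, a muscle actin, from 0.12 to 5.95 and from 0.11 to 525.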

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

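The results here were picked because a named gene rose by at least 2-fold in 1 tissue and fell by at least 2-fold in the other over the same interval. Each tissue has 1 pooled column per stage, so the difference was not tested. Values are the log2 change in explants minus that in progeny.

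From gastrula to early neurula 5 named rows moved apart. The carbonic anhydrase ca12.L rose in explants and fell in progeny, with a difference of 4.099 (24.1 to 148.9 TPM against 15.6 to 4.78). The mesodermal genes pnhd.S and wnt8a.L did the same, with 3.51 and 2.19, from explant levels of 0.91 and 0.89 TPM. The hindbrain gene egr2.L and the neuronal gene elavl3.S fell in explants and rose in progeny, with -2.87 and -2.44. Their explant falls, -1.08 and -1.05, lay just past the limit, and median-of-ratios scaling takes both under 2-fold. From early to mid neurula six3.L rose from 15.9 to 33.7 TPM in explants and fell from 85.7 to 41.7 in progeny, a difference of 2.06. The explant rise, 1.04 on the log2 scale, lay just past the limit, and median-of-ratios scaling takes it under 2-fold.

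From gastrula to mid neurula ccno.L and ccno.S rose in explants and fell in progeny, with differences of 2.87 and 3.76. The rows hoxd1.S, wnt8a.L and wnt8a.S did so too, with 4.07, 3.89 and 3.69, and their explant levels stayed at or below 5.34 TPM. The neural crest gene sox9.S rose from 4.07 to 41.0 TPM in progeny and fell from 8.98 to 3.30 in explants, with -4.26. For myot.L, which was 2-fold apart between the tissues from 8-cell to gastrula, the difference was -4.05. Over all 26351 rows tested, 50 rose in progeny and fell in explants over this interval and 58 did the opposite. The counts were 93 and 50 from gastrula to early neurula, and 4 and 16 from early to mid neurula.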

How the results depend on the processing

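No paired analysis was possible because each group is 1 pooled column that carries no frog number. For the same reason the planned fits on the libraries of 1 contrast, the replicate block, the fits without replicate 1, 2 or 3 and the estimated correlation of the lists were not run. Depth is unknown, so what it limits cannot be stated. Leaving out rows at exactly 0, rows under 5 TPM in the highest column, the summing of homeologs for counts, both neurula stages alone and the 16-cell column in place of the 8-cell column were chosen after seeing the data. Rows at 0 left out kept all 20 counts within 1.5 times. Dropping the filter is no check on counts from 2 columns or on the averaged count. With a pseudocount of 1, rows under 1 TPM in every column cannot be 2-fold apart. The count of rows it could change, that of the difference in change from gastrula to mid neurula, went from 7344 to 7366. Of 140 list values under other settings 139 stayed on the same side of the limits. Of 780 values of named genes under another pseudocount or scaling, 757 stayed on the same side of 2-fold. A change of sign was not possible for a row 2-fold apart. Another pseudocount keeps the sign, and the scaling factors of the 2 tissues differed by far less than 2-fold from gastrula on.

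The cause was not tested for the counts below unless the setting itself changes which rows enter. With a pseudocount of 0.1, which enlarges differences between low values, the count of rows past 2-fold in progeny went from 407 to 1724 (8-cell to 32-cell), from 677 to 1655 (32-cell to blastula) and from 2438 to 4723 (early to mid neurula). In explants it went from 2242 to 4572, 1614 to 3420 and 2300 to 4350 for the same intervals. For explant against progeny it went from 1596 to 3946 at 8-cell, 674 to 2104 at 16-cell, 780 to 2378 at 32-cell, 763 to 2188 at blastula, 1481 to 3377 at gastrula and 4056 to 6770 on average. With at least 5 TPM required, fewer rows enter, and the counts were 213 for progeny from 8-cell to 32-cell, 1550 for progeny from early to mid neurula, and 968, 331, 409 and 383 for explant against progeny at 8-cell, 16-cell, 32-cell and blastula. Median-of-ratios scaling gave 363 for progeny from 32-cell to blastula, and 1459 and 843 for explants over the first and second cleavage intervals. It moved the median of all rows by between -0.20 and 0.32 on the log2 scale within tissues, and by less than 0.1 between the tissues at any stage. The pseudocount damps such shifts for rows with low values. At 8-cell the scaling factors were 0.964 for progeny and 0.789 for explants. There the share higher in explants, among rows 2-fold apart, went from 31.39% to 54.04%. Summing homeologs, which lowers the number of rows, gave 446 for progeny from 32-cell to blastula. With the 16-cell column in place of the 8-cell column the explant count at 32-cell was 76. Over both neurula stages alone the averaged count was 6318. For the averaged comparison the lists outside the limits numbered 23 with the other pseudocount, no filter, median-of-ratios scaling and rows at 0 left out, and 22 with homeologs summed. The other settings were not run on lists.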

Other observations

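All tests in this part were chosen after the results were seen.

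Beyond the comparisons above, stress genes differed in small numbers. At mid neurula 13 of 48 stress and immediate early rows were higher and 2 lower in explants, with sgk1.L and klf2.L 2.08 and 2.54 higher on the log2 scale, and the damage-responsive gadd45a.S was at 34.4 TPM in progeny and 119.7 in explants. The p53 and apoptosis list was under 2-fold in 20 of 24 rows. Of 1986 homeolog pairs whose L row was 2-fold apart between the tissues at early neurula, the S row had the same sign in 85.8%. It was 2-fold apart the same way in 54.1%, and r was 0.685 across all 7202 pairs. Only the L row was picked on its size, so smaller differences of the S row can follow from that choice. In 55 pairs the S row was 2-fold apart the other way. They include eef1a1o, whose S row was listed at 0 in early neurula explants. Another of these pairs is cdh1, E-cadherin, at -1.32 for L and 2.2 for S, and shared reads could not be excluded for any pair.

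Lower neural and higher epidermal transcripts in explants at neurula were weighed here. Somite and muscle genes were lower by more, and the cause of that was not tested. The tables argue against abundant epidermal transcripts taking a share of the total, since the median of all rows at mid neurula was -0.13 while that of pan-neural rows was -1.58. They also argue against later timing alone for the epidermal part. The median epidermal row of explants at mid neurula lay 1.3 (log2) above the highest of the 7 progeny columns. Its bootstrap interval over rows was 0.92 to 1.73. Later timing together with a larger share of epidermis in explants is not excluded by this. At early neurula the values also argue against later timing alone for the pan-neural rows, and other neural lists were not put to this test. The median pan-neural row of explants lay at -0.92 (log2) against the lowest of its own gastrula level and the progeny levels from gastrula on, with a bootstrap interval of -1.36 to -0.39. Of 34 rows 26 lay below that lowest level. The intervals given here are over rows and not over frogs. Many rows are L and S copies of the same gene, so the intervals are likely too narrow. No stage between gastrula and early neurula was sampled, so a passing low there would be missed. At mid neurula timing of the neural part cannot be told apart, as 52.9% of pan-neural rows lay within 2-fold of the progeny range from gastrula on, and the interval of the same median, -1.15 to 0.27, spans 0. A different share of epidermis in the tissue taken also stays open, since the epidermal, ciliated and ionocyte medians rose within 0.84 of each other and tissue and sampling are confounded. An effect of separation from the embryo, the difference that the design names, stays open and was not tested.

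Exact zeros occurred among the most abundant genes. In 13 cases, over 7 rows, a row at 1340 TPM or more in one tissue was listed at 0 in the other at the same stage. These include eef1a1o.S, krt5.7.L and krt5.7.S in neurula explants and cirbp.L in early neurula progeny. A candidate explanation is a failed estimate for abundant transcripts, as 0 of 27089 values from 100 TPM up to 10 times that, and 13 of 1402 values above it, had a 0 in the other tissue. Absence is excluded for cirbp.L, at 5676 TPM at gastrula and 5758 at mid neurula, but for the other rows cannot be told apart, since all those with a later column were at 0 there too. In 6 of the 13 cases, cirbp.L included, the row had been at 100 TPM or more one stage before, which bears against absence without excluding a fall: eef1a1o.S, a translation elongation factor, was at 8784 TPM, krt.S at 9934, Xelaev18002122m at 6066, krt5.7.L at 591 and krt5.7.S at 490.3.

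Large differences kept through cleavage are harder to place. There were 43 rows at least 4-fold apart in the same direction at 16-cell, 32-cell and blastula, 19 higher and 24 lower in explants, and 24 of them were as far apart at 8-cell. For those 24 rows the difference was there at the first stage sampled. They were picked for that, so they say nothing on the source for the other rows. For the set of 43 rows a change with time in culture could not be excluded. The 8-cell median was 80.1% of that at blastula, with a bootstrap interval of 51 to 114%. Picking rows on their blastula difference favours large values there, so this percent leans low. It also rests on the 8-cell explant column, which stood apart from the later cleavage columns. In explants 2242 rows were 2-fold apart between 8-cell and 32-cell, and 76 with the 16-cell column in place of the 8-cell column. Whatever set the 8-cell column apart is therefore part of this percent. A first version that also picked rows by their 8-cell difference gave 119.9%, and it was set aside because it picked rows on the stage it tested. Different mothers behind the 2 sets of columns also stay possible. Of the 247 rows 4-fold apart at 8-cell, 21.5% lacked the same sign at a later cleavage stage. This share cannot decide it, because the rows were picked at 8-cell, where the explant column stood apart. For these rows as a whole neither can be told apart here, because the labels do not say whether frogs were shared and each tissue is 1 set of columns.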
